A study of Homo sapiens with 8 samples.

How the data were processed

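macroH2A1 was profiled by CUT&RUN in HepG2 cells, per the labels' protocols from cryopreserved cells taken 3 days after transfection, with 30 min of digestion. There were 8 libraries, 2 for each combination of siRNA (siControl or siANP32B) and antibody (IgG or anti-macroH2A1). The labels give replicate numbers but do not say whether replicates came from separate cultures, so spreads and p-values measure only the differences between these libraries, which may be technical.

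Per the submitters' processing notes, Trim Galore, Bowtie2, SAMtools, deepTools, SICER and edgeR were used with genome build hg38; versions and settings are not given in the sources used here. The authors deposited 1 domain list for each of the 4 anti-macroH2A1 libraries, called per library, with ends on a 1 kb grid and a score per domain. This deposited score is the caller's own; in the usual output of the SICER reimplementation that the lists are named for it is a scaled log2 enrichment over a control library, but the lists do not say so, nor which control was used. It served only to rank or filter domains. The IgG libraries were not used here.

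The authors' deposited table of differential regions holds, per the file headers, a p-value and a false discovery rate for each of 4474 regions, the fold of a representative window, and the numbers of windows tested, up and down. The fold in the authors' deposited table was read as log2, the convention of edgeR, which the submitters' processing notes name. The false discovery rates equalled a Benjamini-Hochberg adjustment of the p-values over all 4474 regions (largest difference 1.11e-15), so the table includes regions that did not pass. Its other deposited columns are whole numbers of windows, not read counts. It holds no values per library and no standard errors, so no count test of its regions was made here; the number of its columns with values per sample was 0. How libraries were scaled against each other is not given in the sources used here, which matters because a change of scale moves all folds together. The depth of the libraries is unknown, so no interval on a domain or fold is given, and the number of domains a caller finds depends on depth.

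The sign of the folds was settled from the domain lists, as the table does not name the order of its groups. Regions past a false discovery rate of 0.05 were called lower, higher or mixed by the direction the authors' table gives them. Domains were placed on a 1 kb grid over chromosomes 1 to 22, X and Y, each counted up to the last annotated gene, domain or region (3087 Mb in all). Number, covered length and median length per library were compared between groups by an exact permutation test (two-sided); with 2 libraries per group the smallest p is 0.333. Libraries were compared pairwise by the base-pair Jaccard index, and sequence in both libraries of a group and neither of the other was set beside the 2 splits that mix the groups.

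Gene positions came from the RefSeq annotation of GRCh38.p14, the same assembly as hg38, with 59675 genes, of which 20033 are protein-coding. The annotation used here gives gene spans without strand, exons or sequence. Promoters, exons and introns, planned before the data were examined, were therefore replaced by 3 classes (protein-coding gene body, other annotated gene, outside annotated genes), and the siRNA target site was not analysed here. Random placements rotated all domains of a chromosome together, 1000 times, over sequence without gene-free stretches above 3 Mb, which stand in for assembly gaps (2904 Mb kept). Regions with at least 50% of their length in gene bodies were compared by Fisher's exact test with all other tested regions.

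A gene counted as covered when at least 50% of its 1 kb bins lay in a domain. For 22 gene lists written before the data were examined, the share covered in both siControl libraries was compared with 10000 random lists of protein-coding genes matched on length decile, with Benjamini-Hochberg adjustment. The share overlapping a lower or higher region was compared likewise among genes that overlap a tested region, for lists with at least 5 such members. Tested on simulated data, the occupancy test called 3% of 200 lists of 40 genes with no effect and 99.5% of lists with 30 percentage points added, among 20033 genes. The simulated genes were covered independently of each other, so these rates do not hold for families whose members lie side by side.

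Named genes followed a rule fixed before the data were examined: the protein-coding gene with the longest overlap for each of the 15 lower and 15 higher regions with the smallest p-values among called regions in genes, the genes of the 10 longest stretches shared by both siControl libraries, up to 4 members per list (by smallest p-value for change, by largest covered share for occupancy), and ANP32B, MACROH2A1 and MACROH2A2. Any other gene was chosen after its values were seen, and the text says so. Some genes that the rule takes are not reported here.

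Alternatives were a common score limit, lists of equal length by score, domains of at least 5 kb, joining of domains under 10 kb apart, other overlap limits (1 bp, 80%), false discovery rates of 0.01 and 0.1, a minimum log2 fold of 0.5, Fisher's exact test for gene lists, a block by replicate number, and leaving out each library in turn. Added after seeing the data were the omission of chromosomes gained in HepG2 (2, 14, 16, 17 and 20, known from its karyotype, and for gene lists and group-only length also chromosome 6), the better-scored 50% of each list, gene bodies extended by 5 kb on both sides, centring of the folds on their median, and median domain length as a quantity. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.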

Results

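HepG2 cells, a human hepatoblastoma line often used as a model of liver cells, were transfected with a non-targeting siRNA (siControl) or an siRNA against ANP32B (siANP32B), and chromatin carrying the histone variant macroH2A1 was mapped 3 days later by CUT&RUN. In CUT&RUN an antibody directs a nuclease to its target in permeable cells, and the released DNA is sequenced. ANP32B is a histone chaperone, and macroH2A1 is an H2A variant with a large extra domain that is often found on broad, weakly transcribed chromatin. The series asks whether ANP32B affects how macroH2A enters chromatin. Of the 8 libraries, 4 were made with anti-macroH2A1, 2 per siRNA, and each has a list of broad enriched domains. The other 4 were made with IgG and were not analysed here. A further table by the authors compares siANP32B with siControl region by region. Neither kind of file gives read totals, so the depth of each library is unknown.

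After siANP32B, macroH2A1 domains were fewer but longer, and together they covered more of the genome. The 2 siControl libraries held 8623 and 8116 domains and the 2 siANP32B libraries 7530 and 7404, a mean of 8370 ± 359 against 7467 ± 89.1 (SD, n = 2 each). Domains covered 519.3 and 467.4 Mb in siControl and 563.8 and 558.6 Mb in siANP32B cells, or 493.3 ± 36.7 against 561.2 ± 3.64 Mb (SD, n = 2 each). The median domain grew from 38 and 39 kb to 47 and 48 kb, and domains longer than 200 kb rose from 355 and 260 to 470 and 484. The share of the annotated span in domains was 16.8% and 15.1% in siControl and 18.3% and 18.1% in siANP32B libraries.

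For each of these quantities both siANP32B libraries lay on the same side of both siControl libraries. The two-sided exact permutation p was 0.333 for domain number, covered length and median length, the smallest that 2 libraries against 2 can give. The added 67.8 Mb leaned on siControl replicate 2, without which the difference was 41.9 Mb, and the sign turned when only domains above a common score were kept (siANP32B minus siControl, -101 Mb). It was 40.6 Mb without the chromosomes gained in HepG2 and 123 Mb with equal numbers of the best-scored domains per library.

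**Figure D1:**
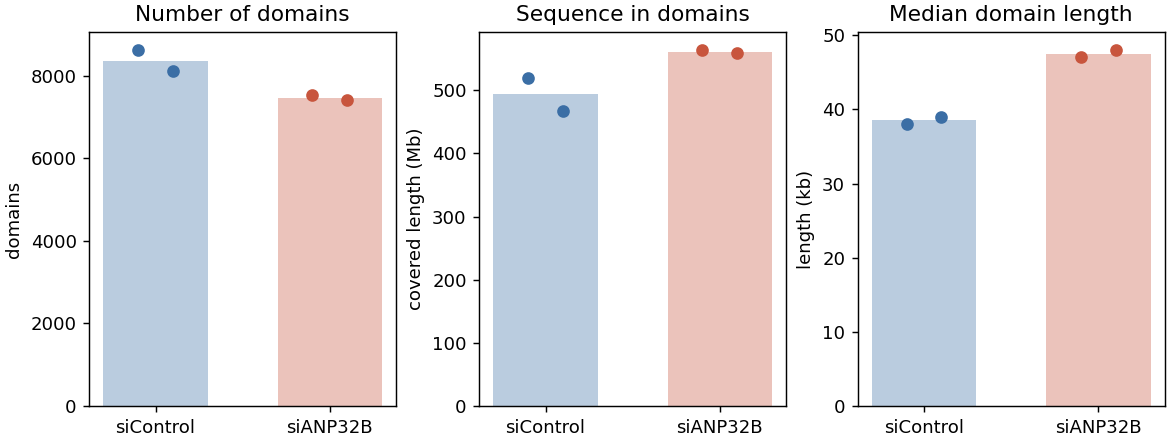
Number of macroH2A1 domains, sequence they cover (Mb) and median domain length (kb) in each library. Points are the 2 libraries of each group and bars their mean. siANP32B libraries reach at most 7530 domains and at least 558.6 Mb, and siControl libraries at least 8116 domains and at most 519.3 Mb.

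Most of the sequence shared by both siControl libraries stayed in domains after siANP32B. Sequence in domains of all 4 libraries came to 314.0 Mb, 82.4% of the 381.2 Mb shared by both siControl libraries. Sequence in a domain of any of the 4 libraries came to 774.1 Mb, so much of it was not called in all 4. Sequence in both siANP32B libraries and neither siControl library came to 45.9 Mb, and the opposite set to 19.4 Mb. Of the 45.9 Mb, 70.3% lay in stretches that touched a siControl domain, so that they extended or joined existing domains, and 11.2 Mb lay in 461 separate stretches. Of the 19.4 Mb found in siControl cells alone, 42.3% touched a siANP32B domain. Between 14.4% and 16.3% of siANP32B domains spanned several siControl domains, whereas 7.29% to 8.95% of siControl domains spanned several siANP32B domains. Between libraries of 1 group the share was 9.43% and 11.9% for siControl and 11.3% and 12.5% for siANP32B.

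The base-pair Jaccard index was 0.629 between the siControl libraries and 0.644 between the siANP32B libraries, against 0.601 ± 0.0225 (SD) over the 4 cross-group pairs, a gap of 0.0359. The 4 libraries can be split into pairs in 3 ways, too few for a test. The 2 splits that mix the groups gave 23.6 against 15.2 Mb and 21.4 against 12.3 Mb of pair-only sequence, and 60.9% to 67.5% of these lengths touched a domain of the other pair. The net gain of 26.4 Mb in siANP32B cells fell to 13.1 Mb without siControl replicate 2 and to 15.6 Mb without chromosomes 2, 14, 16, 17 and 20, which are gained in HepG2 cells. It was 13.0 Mb when chromosome 6, gained in part, was left out as well.

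Within the regions that the authors tested, macroH2A1 was mostly lower after siANP32B. The authors' deposited table lists 4474 regions with a total length of 114.3 Mb, of which 2613 (58.4%) were lower and 171 (3.82%) higher at a false discovery rate of 0.05, 3 were mixed and 1687 did not pass. The median log2 fold in the authors' deposited table was -0.70 over the lower regions, +0.72 over the higher ones and -0.54 over all regions (interquartile range -0.74 to -0.29). Each fold of the authors' deposited table is that of a representative window of its region. A fall by at least 1 on the log2 scale was recorded for 258 lower regions and a rise of that size for 35 higher regions of the authors' deposited table. Of the single windows behind the regions of the authors' deposited table, 31828 of 60658 (52.5%) were counted as down and 2134 (3.52%) as up. No region is narrower than 10 kb, yet 1 region of 75 kb holds 66 windows. Neighbouring windows therefore appear to overlap, and counts of windows are not counts of independent stretches.

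The direction of the contrast is not written in the authors' deposited table; positive folds were read as higher after siANP32B because the regions with positive folds were in domains more often in siANP32B libraries. Since nearly all folds lean one way (89.2% of regions of the authors' deposited table are below 0), the split depends on where 0 is set. As deposited, 6.14% of the 2787 called regions were higher. In the authors' deposited table, 2193 of the 2613 lower regions lay below the median fold of all regions and 420 did not; calls with folds centred on the median cannot be made from this table, so the split under another 0 is unknown.

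**Figure D2:**
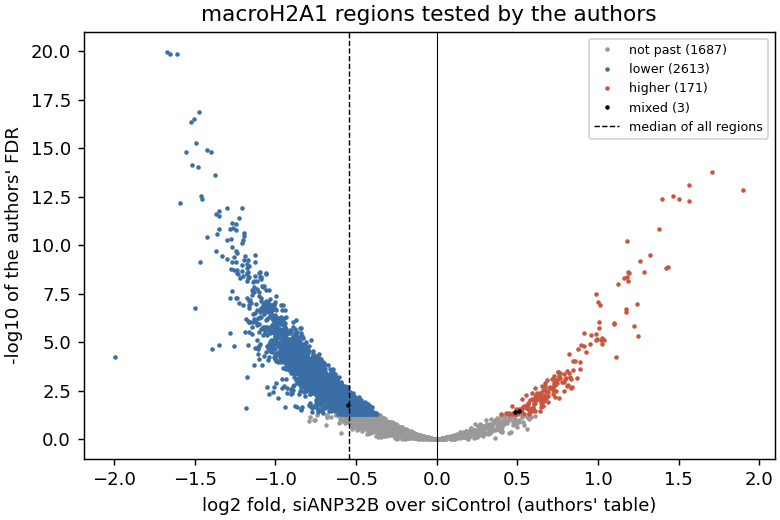
Log2 fold of macroH2A1 signal (siANP32B over siControl) against -log10 of the false discovery rate for the 4474 regions of the authors' deposited table, coloured by call. The dashed line is the median fold of -0.54; 2613 regions are lower and 171 higher.

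Among lower regions that lay in genes, those over PTK2B and CLU on chromosome 8 had the smallest p-values. The first, from 27417001 to 27492000 (hg38), shared 42.4 of its 75 kb with PTK2B, a kinase gene of the focal adhesion family, with a log2 fold of -1.61 (FDR 1.40e-20), and the second, from 27568001 to 27635000 over CLU, which encodes the secreted chaperone clusterin, had -1.65 (FDR 1.40e-20) in the authors' deposited table. Other genes, CHRNA2 and EPHX2, lie between PTK2B and CLU, and the first region also reaches over CHRNA2. These folds leave 32.7% and 31.8% of the siControl signal in the representative window, and all 66 and 58 windows of these regions were down in the authors' deposited table. ABCB11, the bile salt export pump of hepatocytes, overlapped a region of 21 kb with a log2 fold of -1.49 on chromosome 2 (169002001 to 169023000) and ACSM2B, a mitochondrial acyl-CoA ligase, one of 56 kb with -1.42 on chromosome 16 (20557001 to 20613000) in the authors' deposited table. Domains were still called over the CLU, SLC26A9 and ACSM2B gene bodies in all 4 libraries (100% covered), so the lower folds there came without loss of the domain call. Coverage does not measure level, and how the libraries were scaled is unknown, so a true loss within these domains is not shown.

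Among the 15 lower regions in genes with the smallest p-values were also ITGA9, ADGRV1, NEDD9 and COL9A1. In the authors' deposited table the integrin gene ITGA9 had a log2 fold of -1.50, the adhesion receptor gene ADGRV1 -1.37, the adhesion scaffold gene NEDD9 -1.37 and the collagen gene COL9A1 -1.35. At ADGRV1 and COL9A1 most of the region lies beside the gene, with overlaps of 5.20 of 33 kb and 2.08 of 20 kb, and likewise at SLC26A9 (16.5 of 65 kb), UNC13A (13.4 of 37 kb), ACSM2B (19.4 of 56 kb) and CLU (17.8 of 67 kb, the whole gene). The anion transporter gene SLC26A9 (-1.52), the transcription factor gene KLF13 (-1.30), C13orf42 (-1.21) and 3 genes with known roles in neurons, SRRM3 (-1.55), UNC13A (-1.59) and LINGO2 (-1.48), complete this set of the authors' deposited table together with the zinc finger gene ZFP1. At ZFP1 (chromosome 16, 75124001 to 75136000) the log2 fold was -1.46 in the authors' deposited table, and the domain itself disappeared: 55.6% and 38.9% of the gene body was covered in siControl and 0% in both siANP32B libraries. The smallest false discovery rate of the authors' deposited table among all lower regions (1.04e-20) belonged to a stretch outside protein-coding genes on chromosome 10, from 58425001 to 58491000, with a log2 fold of -1.67.

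**Figure D3:**
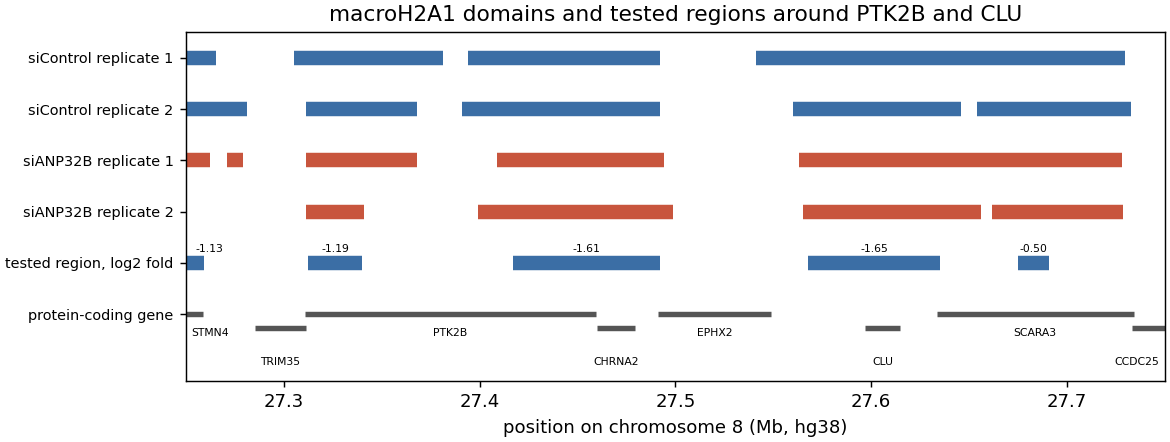
Map of chromosome 8 from 27.25 to 27.75 Mb (hg38), with the domains of each library, the regions of the authors' deposited table with their log2 folds, and protein-coding gene spans. Domains lie over CLU and much of PTK2B in all 4 libraries while the 2 large tested regions have log2 folds of -1.61 and -1.65.

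A small set of regions moved the other way. TSPAN5, a tetraspanin gene, carried the smallest p-value among higher regions in genes, with a log2 fold of +1.56 on chromosome 4 from 98570001 to 98597000 (FDR 7.32e-14), and GRK3, a kinase of G protein-coupled receptors, had +1.90 on chromosome 22 from 25630001 to 25641000 (FDR 1.44e-13) in the authors' deposited table. The GRK3 region had no domain in either siControl library (0% covered) and was fully covered in both siANP32B libraries. MCF2L2 (+1.56), GRB10 (+1.42), which encodes an adaptor of the insulin receptor and is imprinted, OSBPL10 (+1.39), PDZRN3 (+1.32) and AFF3 (+1.29) followed in the authors' deposited table. Domain coverage of the AFF3 gene body was 17.7% and 12.2% in siControl and 66.4% and 37.6% in siANP32B libraries. The other higher genes of the authors' deposited table were SLC4A8 (+1.19), CFAP299 (+1.19), TCF7L1 (+1.18), a transcription factor of the Wnt pathway, CAPN5 (+1.18), SLC25A12 (+1.16), PSTPIP2 (+1.13), TMC7 (+1.00) and NPIPB5 (+0.99), the last from a family of near-identical copies where reads cannot be placed with certainty, with an overlap of 3.54 of 30 kb. The CAPN5 region shares 44.0 of its 94 kb with the gene. SLC4A8 was not uniform, with 27 windows up and 4 down among 54 in the authors' deposited table. Outside genes, the smallest false discovery rate of the authors' deposited table (1.66e-14) was at chromosome 10, 26602001 to 26622000, with +1.71.

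Most lower regions stayed inside domains, and higher regions were in domains more often after siANP32B. At least 50% of the length lay in a domain for 96.7% and 95.3% of lower regions in siControl and for 91.7% and 93.0% in siANP32B libraries, a change of -3.60 points against a pooled SD of 0.976 (n = 2 each). For higher regions the shares were 88.3% and 80.7% in siControl and 99.4% in both siANP32B libraries, a rise of 14.9 points against a pooled SD of 3.80 (n = 2 each). The shares come from the same libraries as the authors' deposited table and set its sign, so they are not independent evidence of it. Of the 114.3 Mb in tested regions of the authors' deposited table, 105.4 Mb lay in domains shared by both siControl libraries. They are only a part of the domain sequence: tested regions of the authors' deposited table took up 27.7% of the length shared by both siControl libraries, 1.35% of the siANP32B-only length and 5.45% of the siControl-only length.

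macroH2A1 domains of control cells lay mostly outside protein-coding genes. Of the sequence in domains of both siControl libraries, 31.2% was in protein-coding gene bodies, against 46.0% ± 0.829 (SD) over 1000 random placements, 18.1% in other annotated genes against 14.8% ± 0.436, and 50.7% outside annotated genes against 39.3% ± 0.700. The siControl-only sequence had a like composition, with 33.2% in protein-coding gene bodies against 44.7% at random. The siANP32B-only sequence did not, with 44.8% against 45.7% ± 1.52 at random. The permutation p was 0.002, the smallest that 1000 placements can give, for the 3 classes of shared domains and for the gene bodies of siControl-only sequence, and 0.567 for the gene bodies of siANP32B-only sequence. Over whole libraries 33.4% and 32.5% of siControl and 36.6% and 34.5% of siANP32B domain sequence was in protein-coding gene bodies.

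Lower regions lay in gene bodies less often, and higher regions more often, than the other tested regions. At least 50% of the length was in a protein-coding gene body for 657 of 2613 lower regions (25.1%) and for 32.0% of the other tested regions of the authors' deposited table (Fisher's exact test, two-sided, p = 6.67e-07). It was for 81 of 171 higher regions (47.4%) against 27.2% of the others in the authors' deposited table (p = 4.46e-08). At a false discovery rate of 0.01 in the authors' deposited table the gap of the lower regions shrank from -6.83 to -3.50 points (p = 0.0105), and that of the higher ones was 19.8 points (p = 3.93e-06). Neighbouring regions are not independent, so these p-values are too small.

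Of the 10 longest stretches shared by both siControl libraries, 9 kept their domain after siANP32B. The longest stretch shared by both siControl libraries spanned 870 kb around IRS1, the insulin receptor substrate gene, on chromosome 2 from 225877001 to 226747000, and was fully covered in both siANP32B libraries. Stretches over BAMBI (574 kb), ABCA9 and its neighbours ABCA8, ABCA6 and ABCA10 (551 kb), MYO3B (536 kb), SMIM38 and MYEOV (526 kb), FGGY and JUN (517 kb) and PHLDA1 (507 kb), and 2 of 512 kb without a protein-coding gene, were covered by 97.4% to 100% in each siANP32B library. The exception was a 790 kb stretch with NPAS3, EGLN3, a prolyl hydroxylase gene of the hypoxia response, and SPTSSA on chromosome 14 from 33664001 to 34454000, which had no domain in either siANP32B library. The caller's scores there were low, 8.25 and 51.6 in the siControl libraries, the first being the lowest of its list. All 3 regions of the authors' deposited table inside it were lower, with log2 folds of -0.48, -0.94 and -0.66.

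The ANP32B gene on chromosome 9 was 0% covered in the 4 libraries, and the genes of macroH2A itself were covered in part in some of them. MACROH2A1 was covered by 31.8% and 4.55% in siControl and 1.52% and 0% in siANP32B libraries, and MACROH2A2 by 26.2% and 0% against 21.3% and 3.28%. None of the 3 overlapped a tested region of the authors' deposited table. Domain coverage does not measure expression, so the extent of the knockdown was not analysed here.

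In control cells the domains were unevenly spread over gene families. At least 50% of the gene body lay in domains of both siControl libraries for 33 of 55 keratin genes (60%, against 16.5% of length-matched random lists), 37 of 73 replication-dependent histone genes (50.7% against 17.4%), 11 of 25 blood and immune genes (44% against 15.2%) and 14 of 34 hepatocyte genes (41.2% against 15.5%). Fully covered members included KRT7 and KRT23 among keratins, H2BC12 and H3C4 among histones, the T cell genes CD8B, LCK and CD3E and the myeloid factor SPI1 among blood genes, and CYP3A4, G6PC1, TAT and CYP7A1, the rate-limiting enzyme of bile acid synthesis, among hepatocyte genes. Covered less often than random lists were zinc finger genes with ZNF symbols (14 of 509, 2.75% against 14.5%), olfactory receptors (30 of 392, 7.65% against 16.8%), cytosolic ribosomal protein genes (1 of 82, 1.22% against 16.7%), cancer-testis antigens (1 of 60, MAGEA11, 1.67% against 16.4%) and clustered protocadherins (0 of 53 against 10.9%).

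These 9 lists passed a two-sided permutation test on 10000 random lists with Benjamini-Hochberg adjustment over 22 lists (adjusted p 8.80e-04 for keratins, histones, zinc finger genes, olfactory receptors and ribosomal proteins, 0.00165 for hepatocyte genes, blood genes and cancer-testis antigens, 0.00978 for protocadherins). Members of a family lie side by side and are not independent. The histone list also holds H1-8 on chromosome 3, a linker histone gene that is not replication-dependent, and counts it as covered. Random lists were matched on gene length and not on chromosome, so a list can differ from them through its chromosomes. MAGEA11, the covered cancer-testis antigen, lies on X, of which domains covered only 2.36% and 1.68% in siControl libraries. Whether cancer-testis antigens differ from other genes of their chromosomes was not tested. Without chromosomes 2, 6, 14, 16, 17 and 20, gained in whole or part in HepG2, the adjusted p was 0.244 for keratins (7 of 27) and 0.738 for histone genes (3 of 18), whose clusters lie there in large part, and 0.0509 for protocadherins. With any overlap in place of 50% of the gene body, the adjusted p was 0.0920 for blood and immune genes and 0.909 for protocadherins, whose gap to random lists was then -2.09 points.

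The other 13 lists did not pass. Nearest to it were housekeeping genes (1 of 37, ACTB, adjusted p = 0.0691), lipid and cholesterol synthesis (0 of 23, 0.137), developmental transcription factors outside the HOX clusters (24 of 105, among them PAX8, TBX4 and GATA5, 0.150), cell cycle genes (1 of 29, CDKN1A, 0.156) and muscle genes (7 of 25, among them DES and CKM, 0.162). Interferon-stimulated genes (8 of 30, 0.214), genes of the secretory phenotype and inflammation (8 of 28, 0.243), HOX genes (10 of 39, 0.253), histone chaperones and macroH2A genes (1 of 26, DAXX, 0.253), imprinted genes (4 of 22, 0.774), cell adhesion and matrix genes (4 of 36, 0.774), neuronal genes (4 of 44, 0.821) and liver transcription factors (3 of 24, FOXA2, CEBPB and HNF4A, 1) had adjusted p-values further away. A single library decided the HOX value: 82.1% of HOX genes were covered in siControl replicate 1 and 28.2% in siControl replicate 2, against 74.4% and 61.5% in siANP32B libraries, and without siControl replicate 2 the list passed (adjusted p = 7.33e-04). The inflammation list also passed without siControl replicate 2 (adjusted p = 0.0176) and the developmental factors without siControl replicate 1 (adjusted p = 0.0282) and with Fisher's exact test against all other genes (adjusted p = 0.0233).

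**Figure D4:**
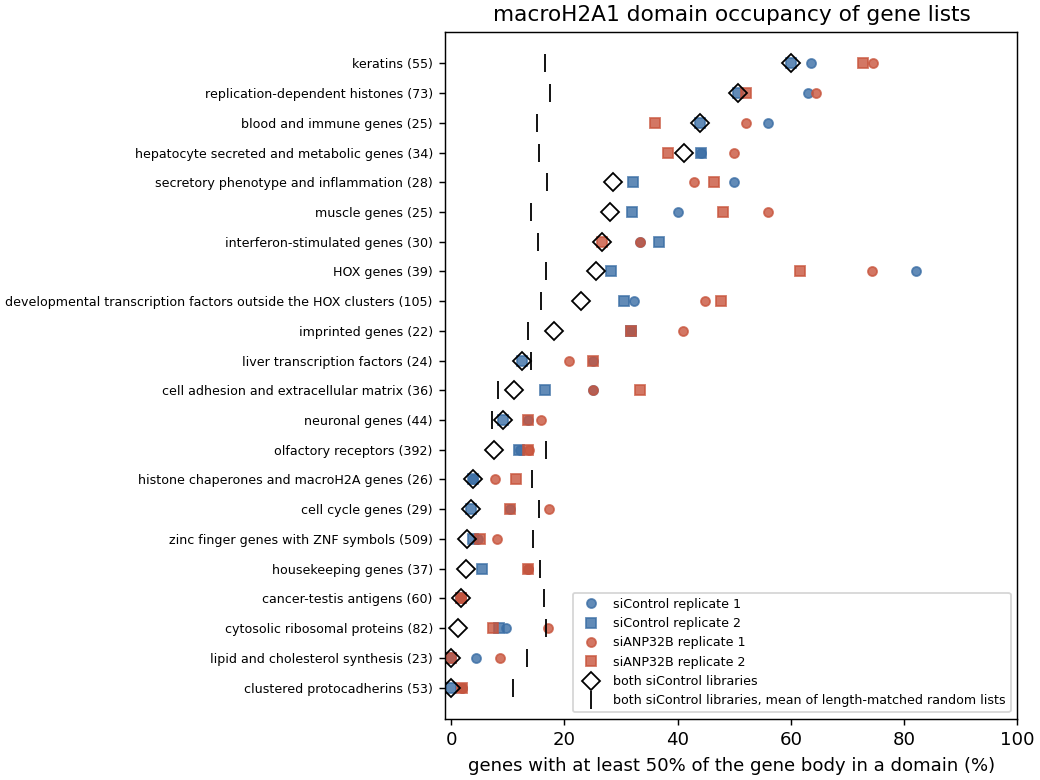
Share of genes (%) with at least 50% of the gene body in a macroH2A1 domain, for 22 gene lists with the number of members in brackets. Coloured points are single libraries, open diamonds the share in both siControl libraries and ticks the mean of length-matched random lists for that share; keratins reach 60% against 16.5%.

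No gene list apart from the protocadherins was singled out by the share of its tested genes in lower or higher regions. Of 1853 protein-coding genes that overlap a tested region of the authors' deposited table, 1125 overlapped a lower and 108 a higher region. All 15 clustered protocadherins with a tested region shared a single one, with a log2 fold of 0.03 in the authors' deposited table, so 0 of 15 overlapped a lower region against 57.6% in matched lists (permutation adjusted p = 0.0040); a result from 1 region says little of the family. The other 9 lists with at least 5 tested members had adjusted p-values of 0.521 to 1 in either direction.

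Within the lists, called genes mostly overlapped lower regions, as over all tested regions. The folds below are those of 1 representative window per region of the authors' deposited table, and often only a small part of the region lies in the named gene. Among hepatocyte genes CYP3A4 (-0.71), the transferrin gene TF (-0.64) and APOB (-0.50) overlapped lower regions in the authors' deposited table, 3 of 10 tested members against 62.0% in matched lists (adjusted p = 0.521). Of 5 liver transcription factors 3 overlapped lower regions, HNF4A (-0.88), FOXA2 (-0.62) and NR5A2 (-0.48), in the authors' deposited table. Cell adhesion and matrix genes were lower in 11 of 13 cases (57.9% in matched lists, adjusted p = 0.521), with LAMA3 at -1.01, CDH11 at -0.96, CDH1, the gene of E-cadherin, at -0.89 and COL5A1 at -0.89 in the authors' deposited table. Neuronal genes were lower in 8 of 14 cases, among them SCN1A (-1.16) and ERBB4 (-1.13), and higher in 1, GABRB1 (+0.74, named after its value was seen), zinc finger genes in 13 of 18, with ZNF703 (-1.27) and ZNF124 (-1.13) first, and blood and immune genes in 5 of 6, with LCK (-0.72) and RUNX1 (-0.65) among them in the authors' deposited table. Keratins were lower in 7 of 10 cases, among them KRT7 at -0.82, and muscle genes in 2 of 6, TNNI2 (-0.84) and CKM (-0.65), in the authors' deposited table. The 7 keratin genes share 4 lower regions, and KRT7, KRT81 and KRT86 lie on 1 of them. Several regions lie almost wholly beside the gene: the overlap was 1.07 of 27 kb at APOB, 8.77% of 41 kb at HNF4A, 0.490 of 11 kb at FOXA2, 0.219 of 43 kb at ZNF703 and 1.02 of 21 kb at TNNI2. At KRT80 (-0.97 in the authors' deposited table) the gene and the region share only 0.005 kb of 20 kb, so that fold says nothing of the gene body. By contrast the regions at TF, NR5A2, CDH1, COL5A1, ERBB4, LCK and RUNX1 lie in the gene in full.

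Developmental transcription factors were lower in 10 of 16 cases in the authors' deposited table, such as TBX15 (-0.78) and PAX5 (-0.61). Among imprinted genes, with too few members for a test, KCNQ1 (-1.30), IGF2 (-0.83) and RTL1 (-0.61) were lower and GRB10 higher in the authors' deposited table. With p-values adjusted over the list alone, 11 in place of 10 regions were lower for developmental factors and 5 in place of 4 for keratins, and the counts for the remaining lists were those over all regions of the authors' deposited table. Few tested regions met the other lists. HOXC12 and HOXC13 shared a lower region (-0.54), and CCL20 (-0.72) and MAGEA11 (-0.54) each overlapped 1 in the authors' deposited table. The olfactory receptor genes OR9Q1 (49.8% of the siControl signal left) and OR11H4 (-0.42) met 3 lower regions between them in the authors' deposited table. The 1 tested member each of the histone, lipid synthesis and cell cycle lists did not pass, and no tested region of the authors' deposited table overlapped a ribosomal protein, housekeeping, interferon-stimulated or histone chaperone gene of these lists.

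By group means, nearly all chromosomes took part in both changes. After siANP32B 22 of 23 chromosomes (1 to 22 and X) were covered more on average, and 18 when siControl replicate 2 was left out. On 14 chromosomes both siANP32B libraries lay above both siControl libraries, an arrangement that chance gives 16.7% of the time for 1 chromosome. All chromosomes come from the same 4 libraries, so this count is no test. Chromosome 20 went from 33.4% and 34.7% to 44.7% and 36.8% and chromosome 16 from 24.5% and 23.8% to 33.9% and 29.5%. The X chromosome was covered least of the 23, with 2.36% and 1.68% in siControl, and less in siANP32B libraries, with 1.13% and 1.44%. In the authors' deposited table lower regions outnumbered higher ones on each of the 24 chromosomes, with median log2 folds from -0.61 to -0.47 on chromosomes 1 to 22 and X.

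On average the 5 chromosomes gained in HepG2 cells were covered more by domains than other autosomes, while their folds were alike. Domains covered 25.4% ± 7.05 (SD) of the 5 gained chromosomes and 15.2% ± 4.73 of the 17 other autosomes in siControl cells (exact permutation test over chromosomes, two-sided, p = 0.00175, adjusted 0.00486), and coverage rose by 4.79 ± 2.82 against 1.89 ± 0.888 points (exact p = 0.00243, adjusted 0.00486). Chromosome 14, one of the 5, was an exception, with 15.1% covered in siControl cells and a rise of 0.267 points, the smallest of any autosome. The median log2 fold of the authors' deposited table averaged -0.51 ± 0.03 on the former and -0.54 ± 0.04 on the latter (exact p = 0.0935, adjusted 0.125), and the gained chromosomes held 16.8 ± 4.30 tested regions per 10 Mb, 1.79 more than the others (exact p = 0.467, adjusted over 4 comparisons 0.467). This grouping of chromosomes was chosen after coverage had been seen, and chromosomes are not replicates of the treatment.

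**Figure D5:**
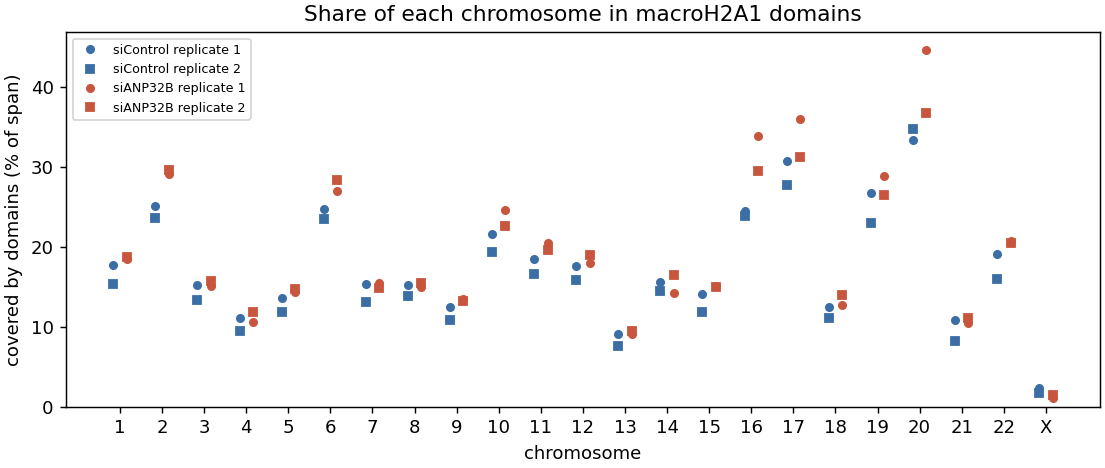
Share of each chromosome's annotated span (%) covered by macroH2A1 domains in the 4 libraries. Chromosome 20 is covered most (up to 44.7%) and X least (at most 2.36%).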

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

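Omission of gained chromosomes, the better-scored 50% of each list, centring of folds, padded gene bodies and the alternatives for median length were chosen after seeing the data. The others were planned. Centring made no new calls and only counted the 2193 lower regions below the median fold. Over 43 results and 227 alternatives, 203 kept their side of the threshold or, without a test, stayed near the main value (5 of them gene lists past the threshold in neither setting, whose difference changed sign), 5 became weaker, 4 stronger, 13 moved and 2 reversed. For domain number, covered length and median length the exact permutation p cannot fall below 0.333, nor the exact sign-flip p below 0.5. These results could not cross the threshold, so they counted as kept whenever the sign held. Covered length (67.8 Mb) thus counted as kept at 123 Mb with equal lists by score. It also did so at 25.2 Mb with the better-scored 50% of each list. Domain number and median length kept their sign under each alternative run. Keeping domains at or above a score of 81.1, the median of all lists, reversed covered length (-101 Mb) and net group-only length (-40.4 Mb) and moved the Jaccard gap to 0.0695; scores ran lower in siANP32B lists (medians 70.1 and 67.5 against 88.9 and 97.7), so this limit removes more of their domains. Net group-only length, 26.4 Mb as deposited, was 51.6 Mb with equal lists by score and 11.8 Mb with the better-scored 50% of each list. It was 15.6 Mb without gained chromosomes and 13.0 Mb without these and chromosome 6. With 1 library left out it was 13.1 to 66.8 Mb, under a looser condition for the group of 1. The cause of these differences was not tested. The gain of domains at higher regions was 24.6 points at 80% overlap and 11.1 to 18.7 with 1 library left out. Gene lists covered more numbered 2 in place of 4 without gained chromosomes and chromosome 6. With the replicate number as a block the differences were -902.5 domains and 67.8 Mb covered (44.5 and 91.2 Mb per number). The exact sign-flip p was 0.5, the smallest for 2 pairs. Net group-only length within each number (gained minus lost) equals the difference in covered length by construction. Its block value, counted among the 13 that moved, is therefore the same 67.8 Mb and no separate alternative. Deviations of same-numbered libraries correlated only weakly, at r = 0.0574 over 13439 bins of 100 kb. In each group, however, replicate 1 held more domains and covered more sequence than replicate 2, so pairing by number is not excluded. Not run for lack of strand and exons were promoters of 2 kb, start sites inside domains and 5 kb upstream; the authors' table could not be refitted without a library. Depth is unknown and limits each domain count.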

Other observations

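The gene examples here were chosen after their values were seen, as were the list tests of gained and lost genes. So were the tests of gained chromosomes, a scaling shift, lower enrichment, the better-scored 50% of each list and a lower level on X. At the level of gene bodies, 444 protein-coding genes were covered by at least 50% in both siANP32B libraries and neither siControl library, and 121 the other way round, while splits that mix the groups gave 296 against 91 and 136 against 107. Of the genes that differ between the groups, 170 of the 444 and 26 of the 121 lie on the 5 chromosomes gained in HepG2. Gained and lost here mean crossing the 50% limit, not the appearance or end of a domain. Gained genes included the developmental transcription factor genes FOXC1, NEUROG1 and SIX3 (0% covered in siControl, 100% in both siANP32B libraries). Coverage of GATA3 was 35.5% and 45.2% in siControl and 90.3% and 71.0% in siANP32B libraries. Also gained were the 4 keratin genes KRT4, KRT79, KRT82 and KRT84, the heart myosin genes MYH6 and MYH7, and HJURP, the chaperone of the centromeric histone CENP-A. Against length-matched genes uncovered in siControl cells, neither developmental factors (7 of 63, 11.1% against 4.03%, permutation adjusted p = 0.154) nor keratins (4 of 20, 20% against 4.37%, adjusted p = 0.154) passed. Olfactory receptors gained less often (2 of 327, 0.612% against 3.84%, permutation adjusted p = 0.0044). Members of a family are not independent and matching was on length, not on chromosome, so that p-value may be too small. Lost genes included ALB, the albumin gene (55.6% covered in both siControl libraries, 16.7% and 33.3% in siANP32B libraries), the chemokine gene CXCL3 (100% against 0%) and OAS1, an antiviral enzyme gene (78.6% and 53.6% against 35.7% and 7.14%). None of these overlapped a tested region of the authors' deposited table. Of the 121 lost genes 14 overlapped a tested region and 11 a lower one, and of the 444 gained genes 40 overlapped a tested region, 16 a lower and 7 a higher one.

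Domains covered more sequence after siANP32B, although regions tested by the authors were mostly lower. The net gain was not confined to the gained chromosomes. Outside them 15.6 Mb of net siANP32B-only sequence remained, and 13.0 Mb when chromosome 6 was left out too. Splits that mix the groups gave at most 8.06 and 7.07 Mb there. The libraries can be split into pairs in only 3 ways, so this comparison is no test. Of the siANP32B-only sequence 70.3% touched a siControl domain (42.3% for siControl-only sequence). Mixed splits gave 60.9% to 67.5%, so this share does not exclude separate new domains. Stretches at least 10 kb from any domain of the other group came to 11.2 Mb siANP32B-only and 10.1 Mb siControl-only. Separate stretches therefore held little of the net gain. Weakly scored domains near the caller's limit stay open: above a common score the covered length changed by -101 Mb, but in the better-scored 50% of each list it rose by 25.2 Mb in siANP32B libraries, and scores of different libraries share no known scale. A difference in depth or background and an effect of siANP32B on macroH2A1 both stay open and were not tested.

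Lower regions outnumbered higher ones in the authors' deposited table by far. Of its called regions 6.14% were higher, with a median log2 fold of +0.72; a downward shift could only remove such calls, so their presence does not measure a shift. For the lower regions, a shift of all folds (median -0.54) and a true loss of macroH2A1 cannot be told apart without counts per library or a spike-in. Lower enrichment over background in siANP32B libraries predicts larger falls where domains score higher; the rank correlation across 4347 regions was -0.0969 (regions are not independent replicates), too weak to decide. An effect of siANP32B on macroH2A1, the difference the design names, stays open beside these, and the knockdown itself was not analysed here.

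The X chromosome had few domains but a density of tested regions like that of autosomes. Of 209 tested regions on X, 103 (49.3%) lay outside the domains of all 4 libraries, against 39 of 4261 (0.915%) on autosomes (Fisher's exact test, two-sided, p = 7.71e-116; regions are not independent). A lower level of macroH2A1 on X stays open: its 13.4 tested regions per 10 Mb lie within the 9.44 to 30.0 of the autosomes, but that number depends on how the authors chose regions, which is unknown. Copy number may enter the domain calls: the short arm of chromosome 6, which is gained in HepG2, was covered at least 1.80 times as much as the long arm in each of the 4 libraries, but the arms also differ in gene content, and X was not tested at another copy number.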
